A study of Mus musculus with 12 samples.

How the data were processed

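Gene expression was measured on 12 Affymetrix arrays of mouse NIH3T3 cells, an established fibroblast line, in 6 groups of 2 arrays. The cells were infected with virus carrying a control vector, Tead2-VP16, Tead2-EnR or Yap. Tead2 is a DNA-binding transcription factor, Yap is a coactivator that binds Tead factors, VP16 is a viral activation domain, and EnR is the repression domain of Engrailed. Per the labels, total RNA was column-purified from cells grown in small dishes and labelled with biotin by the manufacturer's standard protocol. Control cells were harvested at 30% confluency and at complete confluency, Tead2-EnR cells at low density, Tead2-VP16 cells at complete confluency, and Yap and Tead2-VP16 cells also while proliferating at slightly above normal confluency, which is called high density here. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays and no more.

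The deposited values are probe set summaries in intensity units, and the submitters' processing notes name RMA with no version. RMA normalizes between arrays by quantiles and gives log2 values, whereas the deposited values ran from 3.77 to 25980 and were on a linear scale, so log2 was taken before any test. Median intensity lay between 51.9 and 53.7 and the upper quartile between 260.3 and 271.6 across arrays. No detection calls were available, and the number of arrays limits the precision of every value.

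Of 45101 probe sets, 64 were controls, 34945 had exactly 1 gene symbol, 932 had several and 9160 had none. The Entrez identifiers of 34741 probe sets matched a mouse gene table (assembly GRCm38.p6), which was used for names alone and changed 0 symbols. The probe set with the highest mean over the 12 arrays stood for each gene among probe sets with exactly 1 symbol, which left 18193 genes, 9010 of them with more than 1 probe set. No filter on level was applied.

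All 12 arrays were fitted together with 1 mean per group by limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, with 6 residual and 3.45 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over genes within each of 10 comparisons, and a gene was called at an adjusted p below 0.05. The comparisons were the density step in control cells, Tead2-VP16 against control at complete confluency, Tead2-EnR against control at low density, Yap and Tead2-VP16 at high density each against confluent control and against low-density control, Yap against Tead2-VP16 at high density, the density step in Tead2-VP16 cells, and the difference between the 2 density steps. A log2 fold change is the first group minus the second, and errors are SD over 2 arrays or the SE of the fit, as named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

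The 20 gene lists held Yap/Tead targets (a published signature from human tumours), Hippo components, DNA replication, mitosis, growth arrest, extracellular matrix, matrix remodelling, actin and SRF, immediate early genes, cholesterol synthesis, interferon response, hypoxia and glycolysis, amino acid stress and the unfolded protein response, ribosome biogenesis and Myc, inflammatory chemokines, and markers of adipocytes, macrophages, epithelial, endothelial and muscle cells. Of their 539 entries, 515 were measured. Lists were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, and adjusted over all 200 list tests. Of the 91 list tests called, 56 were also called by camera with an estimated correlation. The adjusted p was then much larger, as for mitosis with density in control (0.0020, against 1.8e-30 with the preset correlation).

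Named genes were chosen by rule. They were the 6 genes with the largest rise and the 6 with the largest fall among called genes with at least a 2-fold change, no overlap between arrays and a mean above the median gene of 6.87 in the higher group, leaving out unnamed clones; Tead2 and Yap1; Ccn2 (Ctgf), Ccn1 (Cyr61) and Ankrd1; and up to 4 called members of each list with the smallest adjusted p, or up to 2 members as values where none was called. By chance, 33.3% of genes show no overlap between 2 and 2 arrays. Lists, comparisons, tests, the naming rule and the alternatives below were fixed before the data were examined.

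Correlations of log2 fold changes across genes were computed between pairs of comparisons, each beside 100 simulated data sets with no effect and the same shared arrays. Genes are not independent replicates. The alternatives were a filter keeping genes above the median level, every probe set tested, the mean of a gene's probe sets, the replicate number as a block, a variance trend with a robust prior, quantile normalization repeated, arrays centred on their medians, only the arrays of the comparison, a 2-fold change with no test, each array left out in turn, camera with an estimated correlation, and fry. A split of shared control arrays, 1 to each comparison of a pair, was added after the data had been seen. Groups of 2 allow neither a test for outlying arrays nor a count over other splits of the arrays, and neither was run. Sorting the control probe sets into kinds was done after values had been seen.

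After the files had first been analysed, the fit was tested on simulated data made for the comparison of Tead2-VP16 with control at complete confluency, with 10 sets of 18193 genes and 200 changed genes each. It recovered 84.5% of genes changed by 0.5 on the log2 scale and 99.7% of those changed by 1, and 5.28% of its calls were false. A list shifted by -0.5 was called in 10 of 10 sets, and 0 of 190 other list tests were called. The simulated genes varied independently, with normal noise of the fitted variances, so these rates do not measure error in the real arrays. There, the DNA replication list had an estimated correlation of 0.147, against the preset 0.01.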

Results

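Transcript levels were compared in NIH3T3 fibroblasts that differed in cell density and in whether they carried a control vector, Yap, the activator fusion Tead2-VP16 or the repressor fusion Tead2-EnR. There were 6 groups of 2 arrays: control at low density, control at complete confluency, Tead2-EnR at low density, Yap at high density, Tead2-VP16 at high density and Tead2-VP16 at complete confluency. Log2 intensities of the 2 arrays of a group correlated across genes with r between 0.9976 and 0.9986. Between group means, low-density control and confluent control had the lowest r (0.965), and Yap and Tead2-VP16 at high density had the highest (0.998). The first principal component held 65.2% of the variance and the second 12.5%. All changes below are log2 fold changes unless another scale is named.

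The first comparison asked which genes depended on cell density, with the same control vector at complete confluency and at 30% confluency. Ccn2 (connective tissue growth factor), a secreted matricellular protein and a known Yap/Tead target, fell 34.2-fold, from 11.60 ± 0.02 to 6.51 ± 0.29 (log2 intensity, mean ± SD, n = 2 arrays). Its relative Ccn1 was at -1.47 and -1.49 on 2 of its 4 probe sets, while the others were at 0.19 and 0.22 and not called. Ankrd1, a nuclear ankyrin repeat protein and another known target, fell by 1.91. Among genes that rose, Sned1, a matrix glycoprotein, was 78.9-fold higher in confluent cells (13.20 ± 0.02 against 6.89 ± 0.10, SD, n = 2), and Dcn, the matrix proteoglycan decorin, was 55.9-fold higher. Further large rises were those of Abi3bp (6.22), Postn, the matrix protein periostin (4.97), and Bmf, a pro-apoptotic member of the Bcl-2 family (4.83). Mycn also rose by 5.88, on 1 of its 3 probe sets. The largest falls after Ccn2 were in Cdc6, which licenses replication origins (-3.83), Hmga2, a chromatin protein (-3.49), Cep55, which acts in the last step of cell division (-3.33), Mcm5, a part of the replicative helicase (-3.29), and Bub1, a kinase of the spindle checkpoint (-3.28).

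Genes of the cell cycle fell together with density. All 47 measured mitosis genes were lower in confluent control cells (median -2.56), with Ccna2, cyclin A, at -3.21 and Aurka, a mitotic kinase, at -3.20. All 43 measured DNA replication genes were lower as well (median -2.09), among them Mcm3 (-3.14) and Tk1, thymidine kinase (-3.25). So were all 32 genes of ribosome biogenesis and Myc (median -1.54), led by Odc1, the first enzyme of polyamine synthesis (-2.29), Nop16 (-2.24) and Cad, an enzyme of pyrimidine synthesis (-1.67). These counts were the same adjusted over the list alone. Cholesterol synthesis genes fell in 18 of 20 cases and rose in 1, also adjusted over the list alone, with Idi1 at -2.52, Fdps at -1.75 and Cyp51 at -1.45. Of 33 actin and SRF genes, 18 fell and 6 rose (19 and 6 adjusted over the list alone), including Fhl1 (-2.85), Tagln (-1.48) and Srf itself (-1.58).

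Genes of growth arrest and matrix rose in the same step. Of 32 growth arrest genes, 22 rose and 5 fell (24 and 5 adjusted over the list alone), among them Pdgfra, a growth factor receptor (3.80), Ccng2 (3.37) and Gas6, a ligand of receptor kinases (3.30). Extracellular matrix genes rose in 35 of 42 cases and fell in 1, with Nid2 at 3.54, Ogn at 2.79 and Col3a1, a fibrillar collagen, at 2.28. Matrix remodelling genes rose in 13 of 22 cases and fell in 3, with Reck, a protease inhibitor, at 3.15 and Timp1, another, at -1.81. Interferon response genes rose in 17 of 27 cases and fell in 3, including Gbp2 (2.24), Xaf1 (1.47) and Igtp (1.37). The counts of these last 3 lists were the same adjusted over the list alone. The 12 poly-A spike-in probe sets, which follow the listed order of the samples as described below, differed as well, from 8.30 ± 0.08 to 8.71 ± 0.14 (log2, SD, n = 2). The 3′ minus 5′ difference of the transferrin receptor control probe sets went from 0.98 ± 0.05 to 1.30 ± 0.19. The same difference went from 0.081 ± 0.007 to 0.234 ± 0.017 for the actin control and from -0.231 ± 0.006 to -0.280 ± 0.031 for that of glyceraldehyde dehydrogenase.

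In total, 4748 of 18193 genes were higher and 4150 lower in confluent control cells, 1050 and 944 of them by at least 2-fold. Camera called mitosis (adjusted p = 1.8e-30), DNA replication (2.4e-26), ribosome biogenesis (5.5e-19), extracellular matrix (5.7e-13), cholesterol synthesis (8.2e-09), growth arrest (4.1e-07), interferon response (0.0027), matrix remodelling (0.0034) and actin and SRF (0.0036). In the same order, adjusted p with an estimated correlation was 0.0020, 0.0148, 0.0131, 0.0127, 0.0065, 0.0090, 0.0389, 0.0441 and 0.0394. Amino acid stress and unfolded protein genes fell in 18 of 28 cases and rose in 7, led by Shmt2 (-2.20), Mthfd2 (-2.12), both of folate metabolism, and Psph (-2.12), with an adjusted p of 5.5e-04, or adjusted p = 0.157 with an estimated correlation. The Yap/Tead targets were not called as a list by camera; 10 of 22 rose and 8 fell, also adjusted over the list alone, with F3, tissue factor, at 2.41 beside the falls of Ccn2, Ccn1 and Ankrd1. Their adjusted p by camera was 0.927, and the median (0.033) and mean (-0.15) differed in sign while camera pointed up. Of 23 Hippo components, 6 rose and 6 fell, with Tead4 at -1.82, Wwc1 at -1.34 and Ajuba at -1.17.

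**Figure D1:**
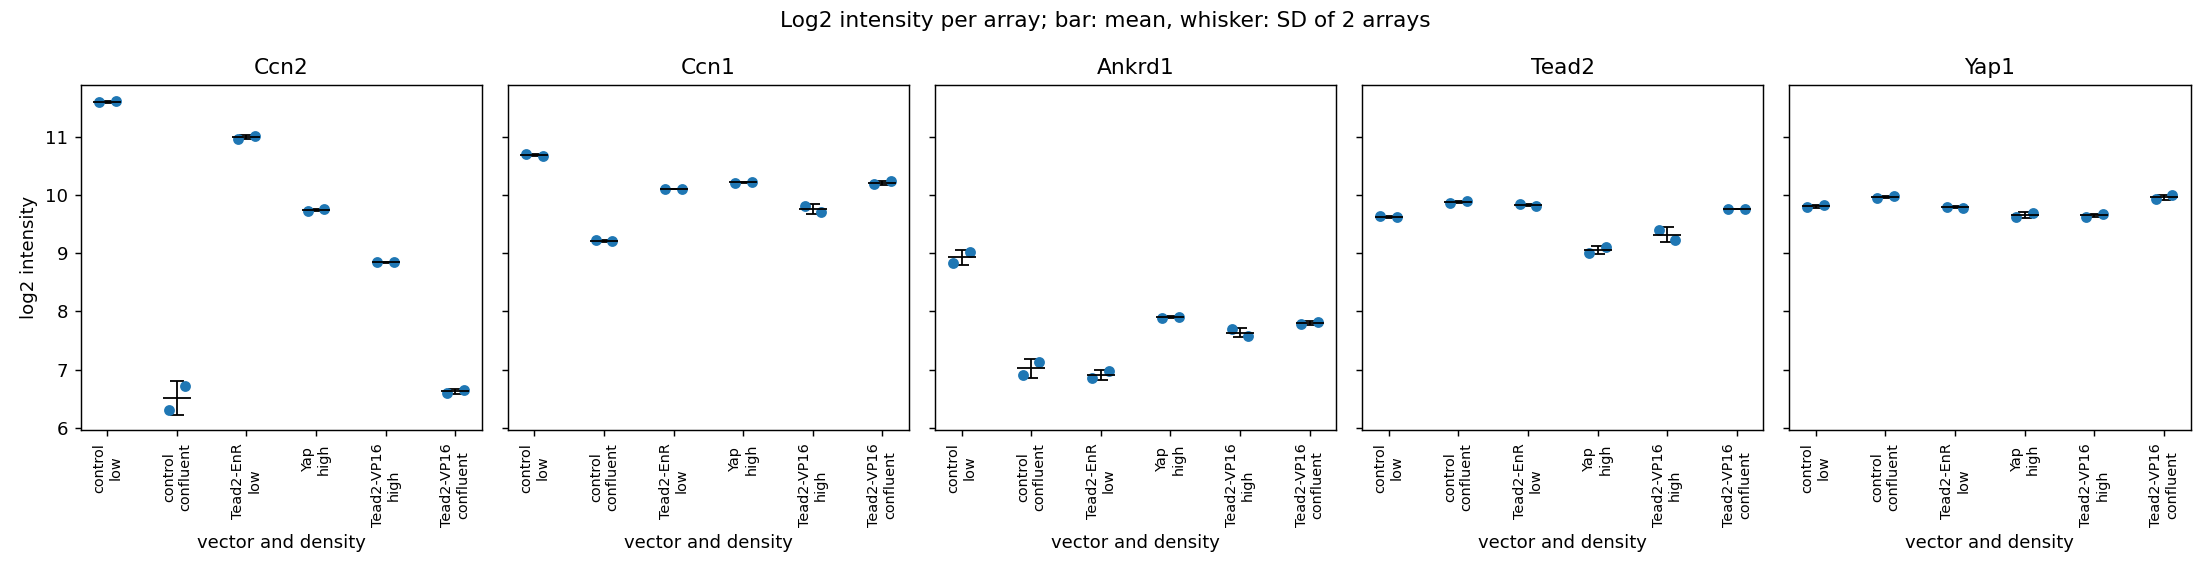
Log2 intensity (vertical axis) of 3 Yap/Tead targets and of Tead2 and Yap1 in the 6 groups of vector and density (horizontal axis); points are arrays, bars are means and whiskers are SD over 2 arrays. Ccn2 was at 11.60 in low-density control, 6.51 in confluent control and 9.74 in Yap cells at high density.

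Tead2-EnR cells were compared with control cells at the same low density, to ask what the repressor fusion changed. Sned1 rose 31.4-fold (11.87 ± 0.03 against 6.89 ± 0.10, SD, n = 2), and Mgp, a matrix protein that inhibits calcification, rose 18.9-fold. Abi3bp (4.85), Islr (4.58) and Bmf (4.21) rose too, as did Mycn (5.18, on 1 of its 3 probe sets). Ankrd1 fell by 2.01 and Ccn2 by 0.61, and Ccn1 was at -0.59 and -0.62 on the 2 of its 4 probe sets that were called. Other large falls were those of C1qtnf3 (-2.32), Gask1b (-2.03), Slit2, a secreted guidance protein (-1.98), the chemokine Cxcl5 (-1.88) and Edn1, endothelin 1 (-1.84).

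Cell cycle genes were lower with Tead2-EnR in nearly every case. All 47 mitosis genes fell (median -0.65), among them Bub1 (-1.01), Kif23, a motor of cell division, and Cenpa, the centromeric histone (-0.91). DNA replication genes fell in 39 of 43 cases and rose in 1 (40 and 1 adjusted over the list alone), with Mcm3 at -0.68 and Tk1 and Prim1 at -0.67 each. All 32 ribosome biogenesis genes fell (median -0.96), with Nop16 at -1.41, Cad at -1.37 and Odc1 at -1.17. Growth arrest genes rose in 21 of 32 cases and fell in 1, including Dcn (3.58), Gas6 (2.79), Ccng2 (2.53) and Trp53inp1, a p53-induced gene (2.27). The mitosis, ribosome biogenesis and growth arrest counts were the same adjusted over the list alone. Beside these gene groups, the spike-in probe sets stood at 8.67 ± 0.05 in Tead2-EnR cells and 8.30 ± 0.08 in control cells (log2, SD, n = 2), and the 3′ minus 5′ difference of the transferrin receptor control at 1.12 ± 0.02 and 0.98 ± 0.05. That of the actin control was 0.154 ± 0.020 and 0.081 ± 0.007, that of glyceraldehyde dehydrogenase -0.262 ± 0.021 and -0.231 ± 0.006, and hybridization controls stood at 11.21 ± 0.07 and 11.10 ± 0.003.

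With Tead2-EnR, 3688 genes were higher and 3292 lower than in control, 451 and 150 of them by at least 2-fold. Camera called mitosis (adjusted p = 3.1e-21), ribosome biogenesis (6.5e-21), DNA replication (3.9e-14) and growth arrest (2.3e-08). In the same order, adjusted p with an estimated correlation was 0.0032, 0.0126, 0.0475 and 0.0062. Extracellular matrix genes rose in 24 of 42 cases and fell in 10, also adjusted over the list alone, with Thbs1, thrombospondin 1, at 2.89, Col6a1 at 1.88 and Ogn at 1.77; adjusted p was 1.4e-04, and adjusted p = 0.0687 with an estimated correlation. Amino acid stress genes fell in 18 of 28 cases and rose in 2 (19 and 3 adjusted over the list alone), with Cth, an enzyme of cysteine synthesis, at -1.58, the cystine transporter Slc7a11 at -1.25 and Trib3 at -1.21; adjusted p was 1.6e-06, and adjusted p = 0.0688 with an estimated correlation. Interferon response genes rose in 11 cases and fell in 2 of 27 (12 and 3 adjusted over the list alone), led by Gbp2 (1.75), with adjusted p = 0.0269, or adjusted p = 0.0845 with an estimated correlation. Immediate early genes fell in 15 cases and rose in 9 of 31 (16 and 9 adjusted over the list alone), with Fosl1 at -1.72, Ptgs2, cyclooxygenase 2, at -1.62 and Egr2 at 1.20. Their adjusted p was 0.0355, or adjusted p = 0.174 with an estimated correlation, and 0.0522 without the first low-density control array. Yap/Tead targets moved both ways, 8 higher and 9 lower of 22, also adjusted over the list alone, with Tgfb2 at 1.78 and F3 at 1.53 beside Ankrd1 (adjusted p = 0.977 by camera; median 0.0094, mean -0.02, camera down).

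At complete confluency, Tead2-VP16 cells were compared with control cells to ask what the activator fusion changed at matched density. Ccn4, a matricellular protein of the same family as Ccn1 and Ccn2, rose 3.79-fold (10.27 ± 0.03 against 8.35 ± 0.05, SD, n = 2). Other rises were those of Pkp2, a desmosomal protein (1.46), Apobr (1.35), Tnc, the matrix protein tenascin C (1.34), and Lbp (1.28). The falls included C1qtnf3 (-2.76), Postn (-2.36), Lum, the proteoglycan lumican (-2.26), Lrrc17 (-1.74), the growth factor Igf2 (-1.63) and Sned1 (-1.53). Ccn1 rose by 0.99 and 0.84 on 2 of its 4 probe sets, while the others were at 0.12 and 0.21 and not called. Ankrd1 rose by 0.78. Ccn2 stood at 6.63 ± 0.04 with Tead2-VP16 and 6.51 ± 0.29 in control (SD, n = 2), a difference of 0.12 with adjusted p = 0.573; it was -0.086 without the first confluent control array and 0.32, which passed the test, without the second.

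Mitosis genes fell further below their level in confluent control, in 28 of 47 cases with 1 rise (39 and 1 adjusted over the list alone, median -0.31), among them Top2a, a DNA topoisomerase (-0.95), Ube2c (-0.55) and Birc5, survivin (-0.48). Amino acid stress genes rose in 16 of 28 cases and fell in 0 (19 and 1 adjusted over the list alone), including Cth (0.95), Chac1 (0.71) and Trib3 (0.61). Of 33 actin and SRF genes, 13 rose and 2 fell (14 and 3 adjusted over the list alone), with Acta2, smooth muscle actin, at 0.94, Fhl2 at 0.75 and Fhl1 at -0.59. Camera called these lists with adjusted p of 5.6e-18, 1.0e-12 and 9.0e-05, or 0.0047, 0.0209 and 0.0148 with an estimated correlation. Beside them, the transferrin receptor 3′ minus 5′ difference stood at 1.501 ± 0.057 against 1.30 ± 0.19 in confluent control (log2, SD, n = 2). Yap/Tead targets rose in 7 of 22 cases and fell in 0 (8 and 1 adjusted over the list alone), with Gadd45a, a growth arrest and DNA damage gene, at 0.90 and the kinase gene Nuak2 at 0.38, whose call was lost in a fit of these 4 arrays alone; adjusted p was 4.2e-04, and adjusted p = 0.0522 with an estimated correlation. Genes of hypoxia and glycolysis rose in 8 cases and fell in 2 of 28 (12 and 4 adjusted over the list alone), led by the glucose transporter Slc2a1 (1.28), with adjusted p = 6.3e-04, or adjusted p = 0.0631 with an estimated correlation.

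There were 920 genes higher and 895 lower with Tead2-VP16 at complete confluency, 23 and 21 of them by at least 2-fold. With arrays centred on their medians, 68.6% of called genes were higher, against 50.7% without. Leaving out 1 array lowered the count of 1815 to 847 without the first confluent control array, 862 without the second, 951 without the first Tead2-VP16 array and 986 without the second. Further lists called by camera lost the call with an estimated correlation. They were DNA replication (1 higher, 6 lower of 43; 1 and 11 adjusted over the list alone; adjusted p = 0.0039, or 0.385 with an estimated correlation), ribosome biogenesis (0 called of 32, also over the list alone; Nop56 at 0.24 and Gar1 at 0.19; adjusted p = 0.0042, or 0.246 with an estimated correlation), immediate early genes (7 higher, 5 lower of 31; 11 and 6 adjusted over the list alone; Dusp1 at 0.93, Fos at -0.78; adjusted p = 0.0199, or 0.141 with an estimated correlation) and chemokines (5 higher, 1 lower of 27, also adjusted over the list alone; Ccl7 at 0.96; adjusted p = 0.0441, or 0.107 with an estimated correlation). Without the second Tead2-VP16 array, adjusted p was 0.0524 for ribosome biogenesis and 0.0831 for chemokines. It was 0.0545 for chemokines without the second confluent control array and 0.0732 for immediate early genes without the first Tead2-VP16 array.

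**Figure D2:**
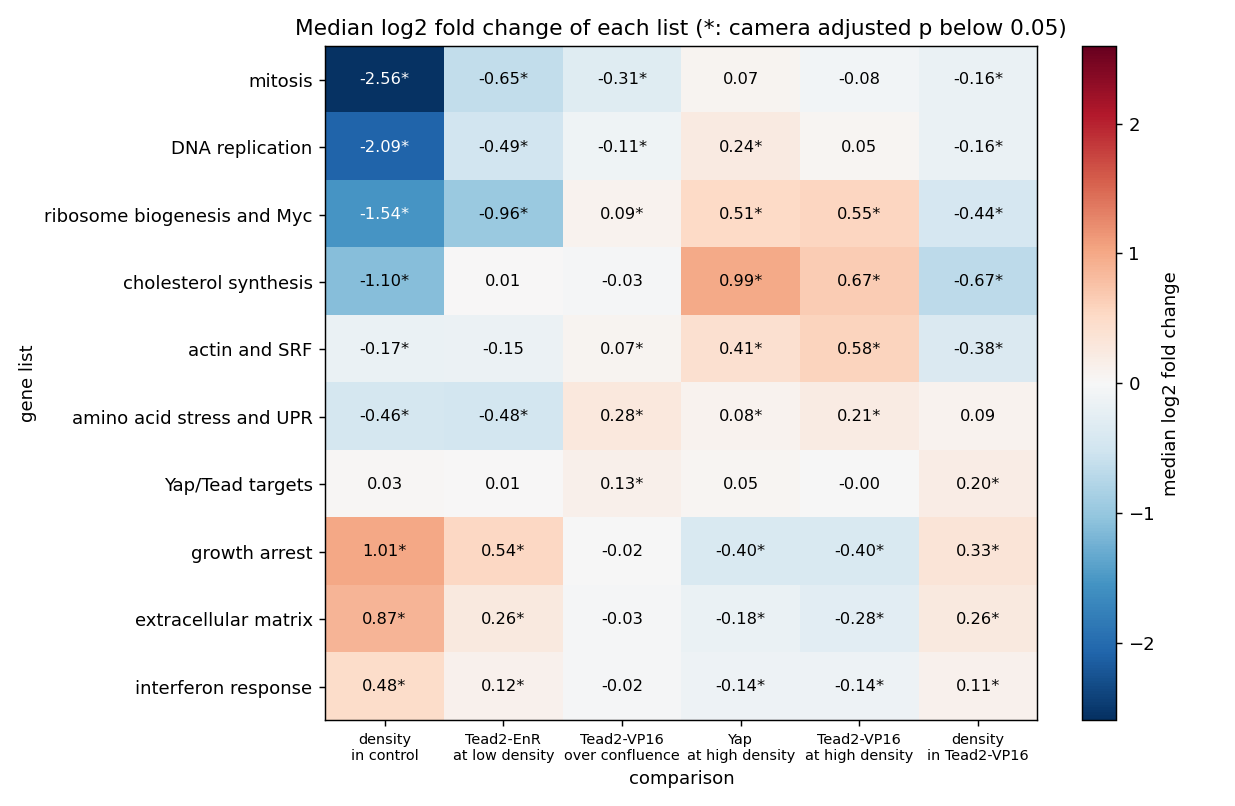
Median log2 fold change of 10 gene lists (rows) in 6 comparisons (columns), shown by colour and number, with a star where camera called the list with the preset correlation. The mitosis median was -2.56 for density in control, -0.65 for Tead2-EnR at low density and -0.31 for Tead2-VP16 at complete confluency.

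Yap cells at high density were set against the nearest control in density, the confluent cells. No control cells were at the same density, so effects of Yap and of density cannot be told apart in this comparison. The labels name the Yap cells, but not the control cells, as proliferating, and growth was not measured. Ccn2 was the gene with the largest rise, 9.40-fold, from 6.51 ± 0.29 to 9.74 ± 0.02 (log2, SD, n = 2). Ccn1 rose from 9.22 to 10.22, with all 4 of its probe sets called, and Ankrd1 rose by 0.88. Fhl1 (2.68), the chemokine Ccl2 (2.65), the actin-binding protein Tagln (2.49), the kinase Prkg2 (2.40) and the phosphodiesterase Pde4b (2.37) also rose. The falls were led by Postn (-3.51), Lum (-3.22), Phex (-2.57), Rspo2, a secreted activator of Wnt signalling (-2.46), Osr1 (-2.37) and Sned1 (-2.34).

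Beside the lists that follow, the actin 3′ minus 5′ difference was 0.122 ± 0.008 with Yap and 0.234 ± 0.017 in confluent control (log2, SD, n = 2). Cholesterol synthesis genes rose with Yap in 18 of 20 cases and fell in 0 (20 and 0 adjusted over the list alone, median 0.99), including Idi1 (1.84), Fdps (1.54), Cyp51 (1.43) and Msmo1 (1.32). Actin and SRF genes rose in 23 of 33 cases and fell in 0 (23 and 2 adjusted over the list alone), with Acta2 at 1.68 and Vcl, vinculin, at 1.27. Ribosome biogenesis genes rose in 27 of 32 cases and fell in 1 (28 and 1 adjusted over the list alone), with Odc1 at 1.07 and Srm at 1.03. Growth arrest genes fell in 23 of 32 cases and rose in 2 (23 and 3 adjusted over the list alone), among them Pdgfra (-1.57), Gas6 (-1.46), Dcn (-1.44) and Gas2 (-1.13). Extracellular matrix genes fell in 20 of 42 cases and rose in 4 (21 and 4 adjusted over the list alone), with Nid2 at -1.92. Immediate early genes rose in 13 of 31 cases and fell in 6 (15 and 6 adjusted over the list alone), with Ptgs2 at 1.70, Dusp6 at 1.55 and Dusp5 at 1.16. In contrast to these lists, mitosis genes were mostly not called, with 10 higher and 4 lower of 47, also adjusted over the list alone; Aurka was at 0.52, Cdc20 at 0.39 and Top2a at -1.06.

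With Yap, 2123 genes were higher and 2633 lower than in confluent control, 93 and 107 of them by at least 2-fold. Camera called cholesterol synthesis (adjusted p = 1.5e-21), ribosome biogenesis (4.2e-17), actin and SRF (1.3e-13), growth arrest (1.4e-09), extracellular matrix (7.9e-06) and immediate early genes (3.8e-04). In the same order, adjusted p with an estimated correlation was 0.0020, 0.0144, 0.0024, 0.0047, 0.0453 and 0.0491. DNA replication genes rose in 22 of 43 cases and fell in 3 (25 and 4 adjusted over the list alone), with Cdc6 at 1.29, Cdt1 at 0.74 and Pcna at 0.66; adjusted p was 2.1e-07, and adjusted p = 0.128 with an estimated correlation. Chemokines rose in 7 of 27 cases and fell in 2 (8 and 3 adjusted over the list alone), with Ccl7 at 2.07 and Ccl9 at 1.11, and with adjusted p = 0.0143, or adjusted p = 0.0643 with an estimated correlation. Calls lost in the same way were those of interferon response (0 higher, 7 lower of 27; 0 and 8 adjusted over the list alone; Ifit3 at -0.61; adjusted p = 0.0615 with an estimated correlation), amino acid stress (9 higher, 4 lower of 28; 10 and 4 adjusted over the list alone; Hspa5 at 0.78; adjusted p = 0.285 with an estimated correlation) and hypoxia (12 higher, 5 lower of 28, also adjusted over the list alone; Adm at -0.95; adjusted p = 0.173 with an estimated correlation). The Yap/Tead targets split into 7 higher and 8 lower of 22 (9 and 9 adjusted over the list alone), with Nuak2 at 1.19 and F3 at -0.79, and adjusted p = 0.784 by camera.

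Tead2-VP16 cells at high density were set against the same confluent control, so density again differed along with the vector. From high density to complete confluency within Tead2-VP16 cells, list medians were -0.67 for cholesterol synthesis, -0.44 for ribosome biogenesis and -0.38 for actin and SRF. They were 0.33 for growth arrest and 0.26 for the extracellular matrix. The labels name the high-density Tead2-VP16 cells as proliferating too. Prkg2 rose by 2.88, Actg2, an actin, by 2.85, Ccl2 by 2.70, Tagln by 2.66, Id1, an inhibitor of differentiation factors, by 2.40 and Ccn2 by 2.33. Postn fell 14.3-fold (8.50 ± 0.04 against 12.34 ± 0.05, SD, n = 2), followed by Lum (-3.11), the linker histone H1f2 (-2.61), the protease Adamts1 (-2.61), Sned1 (-2.59) and Rspo2 (-2.55). Ankrd1 rose by 0.61. Ccn1 was higher by 0.54 on its brightest probe set, but its 4 probe sets went both ways and their mean was at -0.29.

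Beside the lists that follow, the spike-in probe sets stood at 8.43 ± 0.07 with Tead2-VP16 at high density and 8.71 ± 0.14 in confluent control (log2, SD, n = 2). Ribosome biogenesis genes rose in 29 of 32 cases and fell in 0 (29 and 1 adjusted over the list alone, median 0.55), with Srm at 1.06 and Odc1 at 0.87. Actin and SRF genes rose in 22 of 33 cases and fell in 0 (median 0.58), with Vcl at 1.46 and Tpm1 at 1.26. Cholesterol synthesis genes rose in 18 of 20 cases and fell in 0 (median 0.67), with Idi1 at 1.60, Insig1 at 1.29 and Fdps at 1.22. Growth arrest genes fell in 20 of 32 cases and rose in 3, with Dcn at -2.16 and Pdgfra at -1.60. These 3 counts were the same adjusted over the list alone. Extracellular matrix genes fell in 23 of 42 cases and rose in 5 (24 and 5 adjusted over the list alone), with Ogn at -1.28 and Tnc at 1.48. Mitosis genes were again mostly not called, with 5 higher and 11 lower of 47 (7 and 11 adjusted over the list alone), among them Top2a (-1.33) and Cdc20 (0.44).

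In all, 2408 genes were higher and 2485 lower, 99 and 119 of them by at least 2-fold. Camera called ribosome biogenesis (adjusted p = 5.3e-17), actin and SRF (1.3e-16), cholesterol synthesis (4.9e-16), growth arrest (4.7e-09) and extracellular matrix (1.9e-06). In the same order, adjusted p with an estimated correlation was 0.0144, 0.0020, 0.0021, 0.0052 and 0.0389. Calls lost with an estimated correlation were those of amino acid stress (15 higher, 3 lower of 28; 15 and 4 adjusted over the list alone; Dnajb9 at 0.85; adjusted p = 0.164 with an estimated correlation), hypoxia (15 higher, 4 lower of 28; 16 and 4 adjusted over the list alone; Slc2a1 at 0.67; adjusted p = 0.0819 with an estimated correlation), chemokines (7 higher, 2 lower of 27, also adjusted over the list alone; Ccl7 at 1.82; adjusted p = 0.0697 with an estimated correlation), interferon response (0 higher, 8 lower of 27, also adjusted over the list alone; Ifit3 at -0.80; adjusted p = 0.0819 with an estimated correlation) and immediate early genes (13 higher, 8 lower of 31; 14 and 8 adjusted over the list alone; Dusp6 at 1.62; adjusted p = 0.183 with an estimated correlation, and 0.116 without the second Tead2-VP16 array). Yap/Tead targets were split, 7 higher and 6 lower of 22 (7 and 7 adjusted over the list alone; adjusted p = 0.977 by camera; median -0.0042, mean 0.085, camera down).

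The direct comparison of Yap with Tead2-VP16 at high density asked where the coactivator and the activator fusion differed. Higher with Yap were Slurp1 (1.43), C1qtnf3 (1.29), the matrix proteoglycan Ogn (1.26) and Fhl1 (1.18), together with Ccn2 (0.90) and Ccn1 (0.46). The other probe sets of Ccn1, also called in a test over probe sets, were at 0.50, 1.55 and 1.55. Golt1b was at 1.26 and Lcp1 at -1.29, but both calls were lost without the second Yap array (1.22 and -1.09). Mycn was at -1.11 with Yap on 1 of its 3 probe sets, and Tnc at -0.72, a call lost with the mean of its probe sets (-0.20). Ankrd1 differed by 0.27 with adjusted p = 0.206.

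Control probe sets differed between these groups without overlap between arrays: with Yap and with Tead2-VP16, spike-ins stood at 8.59 ± 0.09 and 8.43 ± 0.07, hybridization controls at 10.87 ± 0.09 and 11.01 ± 0.02, and the 3′ minus 5′ differences at 0.122 ± 0.008 and 0.231 ± 0.078 for actin and 1.306 ± 0.068 and 1.228 ± 0.001 for the transferrin receptor (log2, SD, n = 2). DNA replication genes were higher with Yap in 10 of 43 cases and lower in 0 (22 and 0 adjusted over the list alone, median 0.20), and mitosis genes in 4 of 47 with 0 lower (13 and 0 adjusted over the list alone, median 0.14). Cholesterol synthesis genes were higher in 7 of 20 cases and lower in 0 (12 and 0 adjusted over the list alone, median 0.26), with Sc5d at 0.59 and Cyp51 at 0.41. Of 33 actin and SRF genes, 6 were lower with Yap and 1 was higher (17 and 2 adjusted over the list alone), the latter being Fhl1. Camera called these lists with adjusted p of 4.0e-20, 3.9e-11, 5.5e-17 and 4.8e-06, or 0.0252, 0.0126, 0.0020 and 0.0126 with an estimated correlation. Immediate early genes (6 higher, 1 lower of 31; 7 and 3 adjusted over the list alone; Egr1 at 0.66, Phlda1 at -0.50) had adjusted p = 0.133 with an estimated correlation and 0.157 without the first Tead2-VP16 array. Matrix remodelling genes (3 higher, 1 lower of 22; 6 and 3 adjusted over the list alone; Adamts1 at 0.92) had adjusted p = 0.12 with an estimated correlation, and lost the call when any 1 of the 4 arrays was left out (0.0525 to 0.0808). Of the Yap/Tead targets, 6 were higher and 2 lower of 22 (7 and 7 adjusted over the list alone), with Ccdc80 at 0.52 and adjusted p = 0.288 by camera. In a fit of these 4 arrays alone the calls of Golt1b, Lcp1, Ccn1, Cyp51 and Phlda1 were lost.

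Between Yap and Tead2-VP16, 170 genes were higher and 197 lower, 6 and 2 of them by at least 2-fold; 46.3% of called genes were higher, 31.3% with arrays centred on their medians, 64.8% with every probe set tested and 53.1% to 61.6% with 1 array left out. The count of 367 was 95 without the first Yap array, 81 without the second, 86 without the first Tead2-VP16 array and 188 without the second.

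Within Tead2-VP16 cells, complete confluency was compared with high density. The falls were led by Id1 (-3.02), Id2 (-2.75), Tagln (-2.46), Sertad4 (-2.41), Actg2 (-2.39) and Acta1, skeletal muscle actin (-2.22). Ccn2 also fell by 2.22, while Ccn1 rose by 0.45 and Ankrd1 differed by 0.17 (adjusted p = 0.232). The secreted guidance protein Sema3c (1.81), Rspo2 (1.68), the peptide hormone gene Adm (1.66), H1f2 (1.65), Adamts1 (1.62) and N4bp2l1 (1.60) rose. Beside these genes and the lists below, the spike-in probe sets went from 8.43 ± 0.07 to 8.80 ± 0.21 and the 3′ minus 5′ difference of the transferrin receptor control from 1.228 ± 0.001 to 1.501 ± 0.057 (log2, SD, n = 2).

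Cholesterol synthesis genes fell in 18 of 20 cases and rose in 0 (19 and 0 adjusted over the list alone), with Idi1 at -1.43 and Sqle at -1.15. Ribosome biogenesis genes fell in 27 of 32 cases and rose in 1, also adjusted over the list alone, with Rrp12 at -1.08. Actin and SRF genes fell in 20 of 33 cases and rose in 1 (22 and 1 adjusted over the list alone), with Fhl1 at -2.08 and Vcl at -1.22. Growth arrest genes rose in 21 of 32 cases and fell in 2 (23 and 3 adjusted over the list alone), with Txnip at 1.57 and Dcn at 1.26, and extracellular matrix genes rose in 26 of 42 and fell in 3 (28 and 3 adjusted over the list alone), with Postn at 1.48. Mitosis genes fell in 17 of 47 cases and rose in 2 (21 and 2 adjusted over the list alone), with Cdc20 at -0.75. Camera called these lists with adjusted p of 8.3e-18, 1.1e-14, 2.3e-11, 1.1e-11, 6.2e-09 and 1.5e-05. In the same order, adjusted p with an estimated correlation was 0.0020, 0.0179, 0.0032, 0.0032, 0.0198 and 0.0381. DNA replication (3 higher, 17 lower of 43; 4 and 19 adjusted over the list alone) had adjusted p = 0.293 with an estimated correlation. Yap/Tead targets (10 higher, 5 lower of 22, also adjusted over the list alone) had adjusted p = 0.0252, or adjusted p = 0.16 with an estimated correlation, and interferon response (7 higher, 1 lower of 27, also adjusted over the list alone; Ifit3 at 0.60) had adjusted p = 0.0355, or adjusted p = 0.0965 with an estimated correlation. Without the first confluent Tead2-VP16 array they had adjusted p of 0.0509 and 0.137. In this step 2204 genes were higher and 2261 lower, 44 and 64 by at least 2-fold, and the count of 4465 was 2765 without the first high-density Tead2-VP16 array.

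Yap and Tead2-VP16 cells at high density were also compared with low-density control cells, so that density differed along with the vector. Bub1 was at -3.36 with Yap and at -3.57 with Tead2-VP16, Tk1 at -3.23 and -3.26, and Ect2, a regulator of cytokinesis, at -2.96 and -3.21. All 47 mitosis genes were lower with Yap (median -2.54) and with Tead2-VP16 (median -2.73), and so were all 43 DNA replication genes (medians -1.72 and -1.92) and all 32 ribosome biogenesis genes (medians -1.01 and -0.94), also adjusted over the list alone. Beside these lists, the 3′ minus 5′ difference of the transferrin receptor control was 1.31 ± 0.07 with Yap and 1.23 ± 0.001 with Tead2-VP16, against 0.98 ± 0.05 in low-density control, and the spike-in probe sets stood at 8.59 ± 0.09, 8.43 ± 0.07 and 8.30 ± 0.08 (log2, SD, n = 2). In the same order, the hybridization controls stood at 10.87 ± 0.09, 11.01 ± 0.02 and 11.10 ± 0.003, and the 3′ minus 5′ difference was 0.122 ± 0.008, 0.231 ± 0.078 and 0.081 ± 0.007 for actin and -0.258 ± 0.022, -0.284 ± 0.053 and -0.231 ± 0.006 for glyceraldehyde dehydrogenase. Ccn2 was at -1.86 with Yap and -2.76 with Tead2-VP16, and Ankrd1 at -1.03 and -1.29. The gene Dcn was higher by 4.36 and 3.65, Abi3bp by 4.66 and 4.07, Bmf by 4.05 and 3.97 and Sned1 by 3.96 and 3.71. Extracellular matrix genes were higher in 31 and 30 of 42 cases and lower in 2 and 1 (31 and 2 with Yap, 30 and 2 with Tead2-VP16, adjusted over the list alone). With Yap, 4047 genes were higher and 3669 lower, and with Tead2-VP16 4260 and 3546. Camera called these 4 lists in both comparisons, with the extracellular matrix at adjusted p = 4.0e-11 and 3.8e-10 and the others at smaller values.

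The density steps of Tead2-VP16 and control cells were compared by the difference between them, in which the lower density was not the same (slightly above normal confluency against 30% confluency). Mitosis genes fell less in Tead2-VP16 cells, with a positive difference in all 47 (median 2.40), as did all 43 DNA replication genes (median 1.94) and all 32 ribosome biogenesis genes (median 1.04), also adjusted over the list alone. Mitosis genes of Tead2-VP16 cells at high density already lay near confluent control (median -0.08), with little left to fall. Their step was -0.16, against -2.56 in control, so the mitosis difference largely restates the control step. The difference was 2.88 for Ccn2, 2.07 for Ankrd1 and 1.92 for Ccn1. It was negative for 30 of 42 extracellular matrix genes and positive for 1 (31 and 2 adjusted over the list alone), with Postn at -3.49 and Mgp at -3.15, and negative for 19 of 32 growth arrest genes and positive for 6 (19 and 7 adjusted over the list alone), with Gas6 at -2.86 and Ccng2 at -2.48. Camera called these lists with adjusted p of 2.3e-38, 3.2e-33, 1.1e-19, 3.4e-10 and 3.6e-04. In all, 3065 genes had a positive and 3786 a negative difference.

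Fold changes were compared across genes between pairs of comparisons. The Tead2-EnR response at low density followed the density step of control cells, with Pearson's r of 0.81 across genes. Of 6029 genes called in both, 96.5% had the same sign; 3109 were higher in both and 2708 lower in both, where independent calls would give 962 and 751. Because the low-density control arrays were shared, simulated data with no effect gave r of 0.50 on average (highest 0.52). Without effects, that r comes from the shared arrays alone. The covariance was 0.227, against 0.0046 in the simulated data. With no shared arrays, the responses to Tead2-EnR and to Tead2-VP16 at complete confluency were opposed, with r of -0.20 (simulated range -0.025 to 0.025). Simulated genes vary independently. Differences between partner arrays, which hold no group effect, correlated between groups over a wider range, -0.061 to 0.101. Processing differences common to both arrays of a group cancel in them too and are not covered by this range. Of 1263 genes called in both responses, 31.6% had the same sign. The density step had r of -0.64 with Yap at high density (simulated -0.50), where 9.01% of 4062 genes called in both had the same sign, and r of -0.20 with Tead2-VP16 at complete confluency (simulated -0.50), where 33.0% of 1500 had the same sign. Covariances were -0.122 for the pair with Yap and -0.026 for the pair with Tead2-VP16, against -0.0046 in the simulated data for each. Yap and Tead2-VP16 at high density had r of 0.88 (simulated 0.50, highest 0.52) and a covariance of 0.076 (simulated 0.0046). Of 3708 genes called in both, 99.7% had the same sign. Both comparisons set cells at high density against the same confluent control. A shared effect of density may therefore give part or all of this r and of the -0.64 above. The simulated data hold no such effect, and splitting control arrays does not remove it. In a test chosen after the data had been seen, the 2 shared control arrays were split, 1 to each comparison, in both ways. Pearson's r was then 0.76 for density with Tead2-EnR in both ways, -0.14 and -0.16 for density with Tead2-VP16 at complete confluency, -0.588 and -0.592 for density with Yap and 0.78 for Yap with Tead2-VP16 at high density in both ways.

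**Figure D3:**
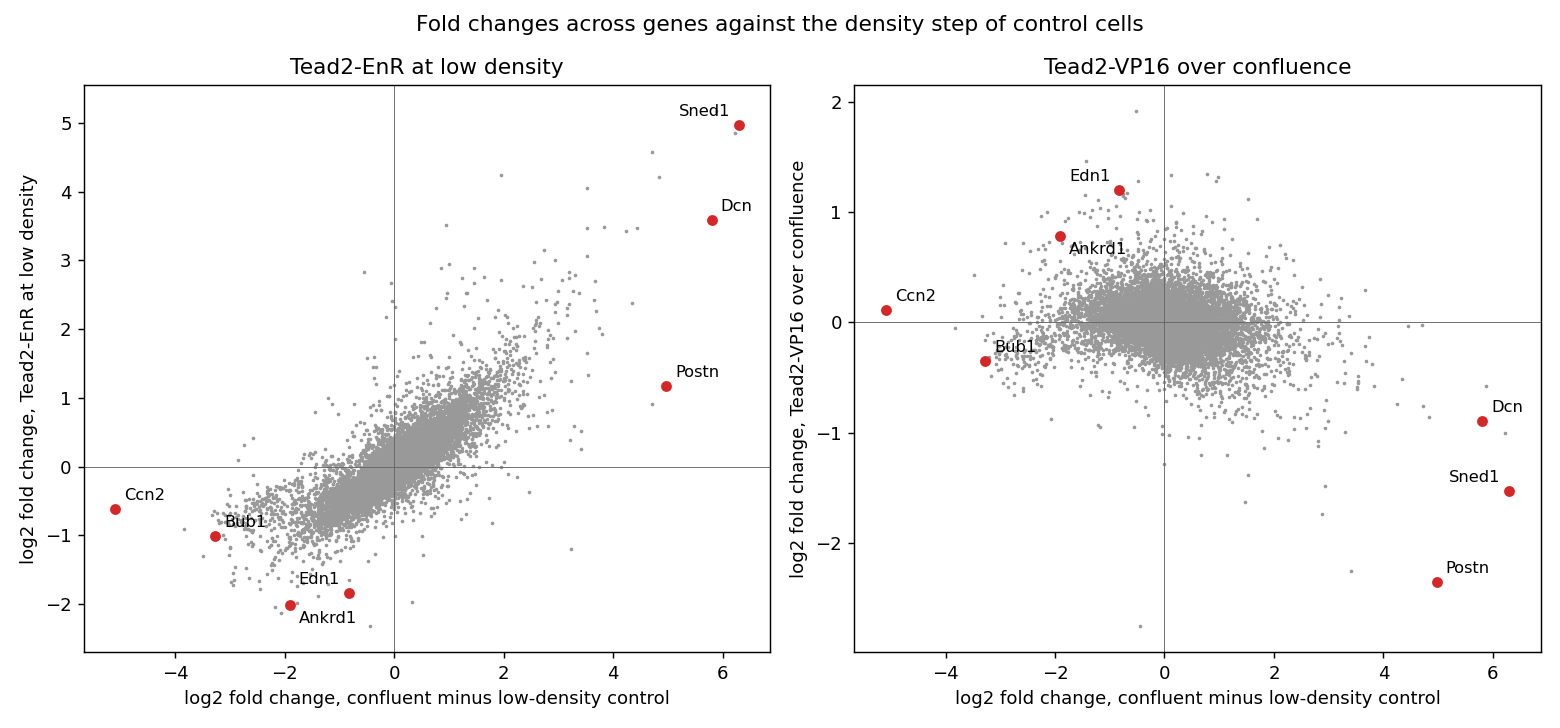
Log2 fold change of each gene in confluent against low-density control (horizontal axes) and with Tead2-EnR at low density (left, vertical axis) or Tead2-VP16 at complete confluency (right, vertical axis); grey points are genes and red points are named genes. Pearson's r was 0.81 on the left and -0.20 on the right, where simulated data with no effect gave 0.50 and -0.50. The covariance was 0.227 and -0.026, against 0.0046 and -0.0046 in the simulated data.

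The labels do not say whether the probe sets of Tead2 and Yap1 lie within the expressed constructs, so their signals do not check the labels. Tead2, with 1 probe set, was at 9.62 ± 0.01 in low-density control, 9.83 ± 0.02 with Tead2-EnR, 9.88 ± 0.02 in confluent control, 9.76 ± 0.002 with Tead2-VP16 at complete confluency, 9.32 ± 0.12 with Tead2-VP16 at high density and 9.05 ± 0.07 with Yap (log2, SD, n = 2). It was higher with Tead2-EnR by 0.21 (adjusted p = 0.0318), a call that was lost without any 1 of the 4 arrays (0.19 to 0.22), and stood at -0.56 with Tead2-VP16 at high density against confluent control (adjusted p = 1.9e-04). Yap1 in Yap cells was at -0.31 against confluent control (adjusted p = 0.0019) on the brighter of its 2 probe sets and at -0.12 on the other (adjusted p = 0.495 over probe sets). On the brighter probe set it differed from Tead2-VP16 cells at high density by 0.0062 (adjusted p = 0.982).

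The lists of markers of adipocytes, macrophages, epithelial, endothelial and muscle cells gave 0 camera calls in 50 tests, 0 also at an unadjusted p below 0.05 and 0 with an estimated correlation, while fry called 12. Single members moved: Lpl, lipoprotein lipase, rose by 1.68 in confluent control, Lyz2, lysozyme, rose by 2.74 with Tead2-EnR, and Krt14, a keratin, fell by 1.21 in confluent control. Tnnt2, cardiac troponin T, fell by 2.90 in confluent control and by 1.45 with Tead2-EnR. The Hippo components gave 0 camera calls in 10 tests, 0 also at an unadjusted p below 0.05 and 0 with an estimated correlation, while fry called 7. Among them Vgll3 fell by 1.02 and Wwc1 by 0.95 with Tead2-EnR, Ajuba rose by 1.04 with Tead2-VP16 at complete confluency, and Tead4 rose by 1.14 with Yap and by 1.09 with Tead2-VP16 at high density.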

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

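The tests on mitosis genes and on Mycn were chosen after their results had been seen, and the spike-in values, though not the test made on them, had been seen before that test was chosen; the pair of comparisons with no shared arrays was added after the data had been examined.

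The change with density differed between Tead2-VP16 and control cells for 6851 genes by the test of the difference between both steps, whose lower densities were not the same. The difference was positive for Bub1 (3.22), Tk1 (3.14), Cdc6 (3.05), Ect2 (3.03), Spag5 (2.98) and Ska1 (2.93), all genes of DNA replication or cell division. It was negative for Mycn (-5.50, 1 of 3 probe sets), Sned1 (-5.24), Abi3bp (-5.07), Bmf (-4.83), Dcn (-4.54) and Islr (-4.25). List medians of the difference were 2.40 for mitosis, 1.94 for DNA replication, 1.04 for ribosome biogenesis, -0.52 for growth arrest and -0.66 for the extracellular matrix. The mitosis value largely restates the control step (-2.56), as these genes were already near the confluent level in Tead2-VP16 cells at high density. Signals of the poly-A spike-in probe sets, which the comparisons do not use, stood above those of low-density control by 0.41 in confluent control, 0.38 with Tead2-EnR, 0.29 with Yap at high density, 0.13 with Tead2-VP16 at high density and 0.50 with Tead2-VP16 at complete confluency (log2). These group means rise in the order in which the samples are listed, starting with low-density control. The labels do not give the order of processing, so its effect cannot be told apart from that of group.

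Tead2-EnR cells at low density differed from low-density control in the same direction as confluent control cells did. Shared low-density control arrays as the whole cause are argued against by a pair of comparisons with no shared arrays, Tead2-EnR against control and the density step in Tead2-VP16 cells, whose fold changes correlated across genes with r of 0.301, above the highest of 100 simulated data sets with no effect (0.023). Simulated genes vary independently. Differences between partner arrays correlated between groups at -0.061 to 0.101, a wider range. Variation common to both arrays of a group cancels in them, so this range sets no bound on processing differences between groups. Spike-in signals rose in both comparisons, from 8.30 to 8.67 and from 8.43 to 8.80 (log2). A part of the r of 0.301 from such differences stays open. Fewer transcripts of all kinds per unit of RNA was the other explanation set. After the spike-in rise of 0.375 was subtracted, 8.84% of called genes still lay over 0.5 above 0, short of the bound set beforehand, and 47.2% lay over 0.5 below. The bound was hard to reach, as the median absolute change of called genes was 0.43. A uniform fall is removed by normalization between arrays (median of all genes -0.011) and leaves r unchanged. The 3109 genes higher and 2708 lower in both comparisons argue against it as a source of the shared direction. Whether transcript amounts fell as well stays open, since the amount of spike-in added to each sample is not in the labels. An effect of the repressor fusion on the genes that respond to density stays open as a biological explanation that was not separately tested.

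Mitosis genes in Yap and Tead2-VP16 cells at high density, labelled as proliferating, lay near the level of confluent control cells and far below that of low-density control. Signals at the bottom of the scale are argued against by the median level of these genes in confluent control, 7.55 against 6.87 for the median gene, with 36 of 47 above that. The lowest was at 5.97, above the lower quartile of all genes' means (4.87). Without detection calls, a floor particular to a single probe set stays open. Fewer transcripts of all kinds as the whole cause are argued against by the spike-in rise over low-density control, at most 0.288 in these groups. The mitosis medians were -2.54 and -2.73. That use of the spike-ins holds only if equal amounts were added, which the labels do not say. Without them, normalization between arrays would remove a fall of all transcripts alike. The median of all genes against low-density control was -0.0069 with Yap and 0.0083 with Tead2-VP16. This too argues against such a fall as the whole cause of the mitosis medians. The lists not called against confluent control do not show that levels were equal. A slowing of division at this density may account for the pattern as a hypothesis, since growth rate was not measured and the labels alone name these cells as proliferating.

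The rise of Mycn with density and with Tead2-EnR rested on 1 of 3 probe sets, which went from 7.39 to 13.27 with density. The other probe sets changed by at most 0.189, one from 5.27 to 5.20 and one from 3.74 to 3.93 (log2). A signal from another transcript, or from 1 form of the Mycn transcript, is a candidate explanation resting on the first of these alone, whose mean lies at percentile 35.1 of probe sets, against 14.9 for the second, too dim to count. Low signals leave open that they respond weakly. Nothing said of Mycn here extends to the gene as a whole.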

How the results depend on the processing

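All alternatives below were planned, except the split of shared control arrays, chosen after the data had been seen. The list tests not called, other than those of the Yap/Tead targets, were followed only as a count of calls, which was decided after values had been seen. Counts of called genes stayed within 1.5 times their value with the replicate block (1630 against 1815 for Tead2-VP16 at complete confluency and 339 against 367 for Yap against Tead2-VP16), quantile normalization repeated, arrays centred on their medians and the mean of a gene's probe sets. Differences between partners correlated across genes at -0.061 to 0.101 over 15 pairs of groups. Poly-A spike-ins were higher in the second array of every group, from 8.64 and 8.71 with Tead2-EnR to 8.65 and 8.95 with Tead2-VP16 at complete confluency (log2). A link between arrays of the same replicate number therefore stays open. The median of all genes moved by at most 0.054 between scalings. Arrays give no depth, and signals near background limit dim genes.

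Testing every probe set, with more features tested, gave higher counts: 17488 for density in control, 12393 for Tead2-EnR, 7758 for Yap and 8429 for Tead2-VP16 at high density, 781 for Yap against Tead2-VP16, 7321 for density in Tead2-VP16, 14816 and 14690 for Yap and Tead2-VP16 against low-density control and 12038 for the difference between density steps. Changes of at least 2-fold with no overlap between arrays and no test gave fewer genes: 1994 for density in control, 44 for Tead2-VP16 at complete confluency, 601 for Tead2-EnR, 200 for Yap and 218 for Tead2-VP16 at high density, 10 for Yap against Tead2-VP16 (8 of them called by the test), 108 for density in Tead2-VP16, 1204 and 1307 against low-density control and 1467 for the difference. For Tead2-VP16 at complete confluency the count was 2795 with a variance trend and robust prior, 859 with only its arrays and 847 to 986 with 1 array left out. For Yap against Tead2-VP16 it was 986 with genes above the median level, 1058 with the trend and robust prior, 78 with only its arrays and 81 to 188 with 1 array left out. The density step in Tead2-VP16 gave 2765 to 3411 with 1 array left out. Fewer arrays lower the residual degrees of freedom, and a lone array is then assumed to vary like the other groups. For the trend and robust prior the cause was not tested.

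Of 200 list tests, camera called 91, or 56 with an estimated correlation, and fry, which tests each list alone, called 144. With 1 array left out there were 85 to 91 calls. Of the 91, the filter on level lost 6, the mean of probe sets 3 and the block 3. For the Yap/Tead targets, whose list camera did not call in these comparisons, the direction turned, with adjusted p of 0.22 for density in control, 0.0825 for Tead2-EnR and 0.0142, a call, for Tead2-VP16 at high density with fry; 0.963 for density in control and 0.909 for Tead2-VP16 against low-density control with the filter on level; 0.976 and 0.995 for the same comparisons with the mean of probe sets; and, for Tead2-VP16 at high density, 0.941 without the first and 0.998 without the second confluent control array (0.936 to 0.9998 over all arrays left out). Over all alternatives the adjusted p was 0.22 to 0.976 for density in control, 0.0825 to 0.994 for Tead2-EnR, 0.0142 to 0.9998 for Tead2-VP16 at high density and 0.122 to 0.995 for Tead2-VP16 against low-density control. In comparisons where the direction stayed, fry called this list where camera had not, with adjusted p of 4.5e-04 for Yap at high density (up to 0.86 over all alternatives), 5.7e-04 for the difference between density steps (up to 0.687), 0.0026 for Yap against low-density control (up to 0.895) and 0.0208 for Yap against Tead2-VP16 (up to 0.481). The cause was not tested.

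Of 748 called values of named genes, the 2-fold rule with no test lost 313, the mean of probe sets 33, only the arrays of the comparison 52, every probe set 24, arrays centred on their medians 8, quantile normalization 7, the block 6 and the trend with robust prior 6, and 74 lost the call in at least 1 fit with an array left out. With the mean of a gene's probe sets, whose members disagree, Ccn1 turned to -0.29 for Tead2-VP16 at high density and 0.087 for Yap against low-density control, Cd53 to -0.0085 for density in Tead2-VP16 and Egfl7 to -0.011 for Yap against low-density control. Ccn2 with Tead2-VP16 at complete confluency, not called, was -0.086 to 0.32 with 1 array left out. Tead2 with Tead2-EnR was 0.19 to 0.22 with 1 array left out, with the call lost each time. Yap1 between Yap and Tead2-VP16, 0.0062, was -0.022 with arrays centred on their medians and -0.027 to 0.039 with 1 array left out.

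With the filter on level, r across genes was 0.83 for density with Tead2-EnR, -0.65 for density with Yap, -0.24 for Tead2-EnR with Tead2-VP16 at complete confluency and 0.92 for Yap with Tead2-VP16. The mean of probe sets gave -0.21 for Tead2-EnR with Tead2-VP16. Leaving out 1 array gave 0.79 to 0.81 for density with Tead2-EnR, -0.23 to -0.18 for density with Tead2-VP16, -0.64 to -0.62 for density with Yap, -0.21 to -0.19 for Tead2-EnR with Tead2-VP16 and 0.85 to 0.89 for Yap with Tead2-VP16. With the shared control arrays split between the comparisons, in both ways, r was 0.7599 and 0.7612 for density with Tead2-EnR, -0.14 and -0.16 for density with Tead2-VP16, -0.588 and -0.592 for density with Yap and 0.779 and 0.781 for Yap with Tead2-VP16; single arrays are also noisier than means of 2. All kept their sign, and the cause of these moves was not tested.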

Other observations

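The test on cholesterol synthesis genes and the choice of the opposed genes named here came after the results had been seen; before the test of opposite regulation, the opposite directions of some lists had been seen, though not the overlap.

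Some genes moved in opposite directions with the repressor and the activator fusion, each against its own control. Lower with Tead2-EnR and higher with Tead2-VP16 at complete confluency were Edn1 (-1.84 and 1.20), Ifrd1, a regulator of transcription (-1.13 and 1.15), Rassf5, a Ras association domain gene (-1.42 and 1.02), the chemokine Ccl7 (-1.14 and 0.96) and Cth (-1.58 and 0.95). Higher with Tead2-EnR and lower with Tead2-VP16 were Sned1 (4.97 and -1.53), Ptx3, a secreted pattern recognition protein (1.59 and -1.20), Postn (1.17 and -2.36), Scrg1 (1.12 and -1.38), Gas6 (2.79 and -0.99) and Fgfr2, a growth factor receptor (1.63 and -0.93).

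Opposite regulation of the same genes by both fusions is a hypothesis that was tested by counting. There were 402 genes lower with Tead2-EnR and higher with Tead2-VP16, where independent calls would give 166, and 166 genes lower with both, where independent calls would give 162. In the other direction, 462 genes were higher with Tead2-EnR and lower with Tead2-VP16 (181 if independent), and 233 were higher with both (186 if independent). These counts are consistent with opposite regulation for a part of the genes. Density differed between the fusions, which leaves a response that depends on density open, and binding of Tead2 was not measured.

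Regulation by Tead2 binding was also set as a hypothesis for the cholesterol synthesis genes, which fell with density in control and rose in Yap and Tead2-VP16 cells at high density. With Tead2-EnR at low density their median change was 0.0058, with 3 higher and 1 lower of 20. Those called were Tm7sf2 (1.27), Hsd17b7 (0.48), Dhcr7 (0.29) and Idi1 (-0.26); the call of Dhcr7 was lost without the first control array (0.20) or the second Tead2-EnR array (0.25), and that of Idi1 without the second control array (-0.23) or the first Tead2-EnR array (-0.22). On this scale the repressor fusion thus left the list without a common fall at low density, which argues against a fall particular to this list at that density. A fall of all transcripts together, left open above by the spike-in rise of 0.375, would not be seen in these values. With Tead2-VP16 the list was not called by camera at complete confluency (1 higher and 2 lower of 20, median -0.031, adjusted p = 0.776). At high density against confluent control its median was 0.67, but density differed there too. From high density to complete confluency within Tead2-VP16 cells its median was -0.67 (0 higher and 18 lower of 20). The rise of 0.67 thus cannot be told apart from an effect of density. Yap and Tead2-VP16 cells, both labelled as high density, differed in this list. With Yap, 7 of 20 were higher and 0 lower (median 0.26, camera adjusted p = 5.5e-17, or 0.0020 with an estimated correlation). A part of the difference from confluent control with Yap thus went with the vector at the same labelled density, which does not show Tead2 binding. Regulation by Tead2 that depends on density stays open, as no control was at high density.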
